A study of Mus musculus with 43 samples.

How the data were processed

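Poly-A RNA of 43 mouse back-skin samples was sequenced with paired reads of 151 bases. The deposited table gives 1 signal per gene and sample, which the authors made with STAR, HTSeq and DESeq2 on build mm10; per the labels no version, annotation or filter is stated. The signal is a read count divided by 1 size factor per sample, and is called a normalised read count or value. Every value of a sample is a whole multiple of its smallest step, so whole reads were recovered for 100% of values within 0.01, with size factors from 0.6735 to 1.7503. The table holds 23256 genes by symbol only. Of these, 16763 (72.1%) match a symbol in reference lists of gene names, RefSeq among them. Positions came from GENCODE vM21 on GRCm38, for 15388 of the 19170 genes tested. Depth ran from 18.49 to 37.76 M reads, and the 10 most abundant genes took between 4.89% and 14.53% of a library.

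Samples were grouped by the strain and UVB regimen in their labels, and no technical replicates were merged, since the lowest chi-square per gene between replicates was 16.9. Genes with a value of at least 10 in at least 4 samples were kept, which left 19170. The main test was limma-trend (version 3.58.1, in R 4.3.3) on log2(value + 1), with 1 mean per group over the 43 samples, two-sided, and Benjamini-Hochberg adjustment at 0.05. The pseudocount of 1 shrinks fold changes of genes with low counts. There were 12 comparisons of 2 groups, 4 interactions and 1 mean of chronic against acute UVB over the 3 strains. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 36 lists within a comparison; an estimated correlation and fry, which tests a list without setting it against other genes, were the alternatives. A list's score in a sample is the mean over its genes of log2(value + 1) centred per gene. Scores of 7 lists were compared in the 12 comparisons of 2 groups by exact permutation, two-sided, 84 tests in all.

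Named genes follow a rule with 3 parts: genes with adjusted p below 0.05, a mean of at least 100 in the higher group and no overlap between the groups, taken by largest log2 difference, up to 8 in each direction for 6 main comparisons and 3 for the others, with predicted models and receptor segments left out; up to 4 members with the smallest adjusted p of each list described; and 21 genes fixed by name. The lists, the comparisons, the rule and the settings listed next were chosen before the data were examined. A gene with no reads in a group was given a floor of 3 reads over that group, which covers counting error only. A fold written as at least sets the arithmetic mean of the other group against that floor. It is not a lower bound on the limma difference.

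The settings varied were pseudocounts of 0.5 and 8, no filter and a filter at 50, TMM scaling and quantile normalization, only the compared groups in the fit, a covariate for sample numbers of 46 or above, sample quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads (4261 and 4990 genes for acute UVB in NZM, against 4097 by limma), a threshold of 0.01, and leaving out each replicate in turn. The hair follicle score as a covariate, and leaving out the 9 libraries with that score above 5, were added after seeing the data. The steps were tested on simulated data before use. These had the real groups and depths, but genes were drawn independently and few were changed, in a single group. With the change in NZM after acute UVB, limma recovered 76% of genes changed 4-fold and 39.8% of those changed 2-fold. Such rates do not describe the real comparison, where far more genes were called. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.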

Results

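RNA sequencing measured poly-A RNA in 43 back-skin libraries from female mice aged 10 to 13 weeks. The libraries formed 9 groups, from 3 strains and 3 regimens of UVB, the medium-wave ultraviolet light that causes sunburn. NZM stands for the lupus-prone mouse line NZM2328 of the series title. The labels define neither iNZM, a name used in this field for NZM2328 mice without the type I interferon receptor, nor the strain behind WT. Acute UVB was 1 exposure of 300 mJ/cm2, chronic UVB was 5 daily exposures of 100 mJ/cm2, and skin was sampled 24 hours after the last one. Each group held 5 libraries, except that iNZM without UVB and WT without UVB held 4 each. Depth ran from 18.49 to 37.76 M reads per library, with a median of 24.44 M. As far as the labels say, no libraries were paired, and they do not state that each came from a separate animal.

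Because the labels leave iNZM undefined, the receptor gene was compared between the strains. Ifnar1 encodes a chain of the type I interferon receptor (ENSMUSG00000022967.13, chromosome 16, 91485238 to 91507441 in build GRCm38). Its normalised read count was 878 ± 126 (SD, n = 15) in NZM, 947 ± 189 (n = 14) in WT and 420 ± 85.5 (n = 14) in iNZM. The highest iNZM library, at 579, lay below the lowest NZM library, at 716, and the lowest WT library, at 758. On the log2 scale iNZM differed from NZM by -1.10 ± 0.14 (SE) without UVB, -1.04 ± 0.13 after acute UVB and -1.13 ± 0.13 after chronic UVB. The limma adjusted p were 5.62e-05, 1.52e-05 and 7.57e-06, and became 0.0587 after acute and 0.0676 after chronic UVB when only the compared groups were fitted. Ifnk and Ifnb1, 2 interferon genes fixed in advance, were not analysed here.

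**Figure D1:**
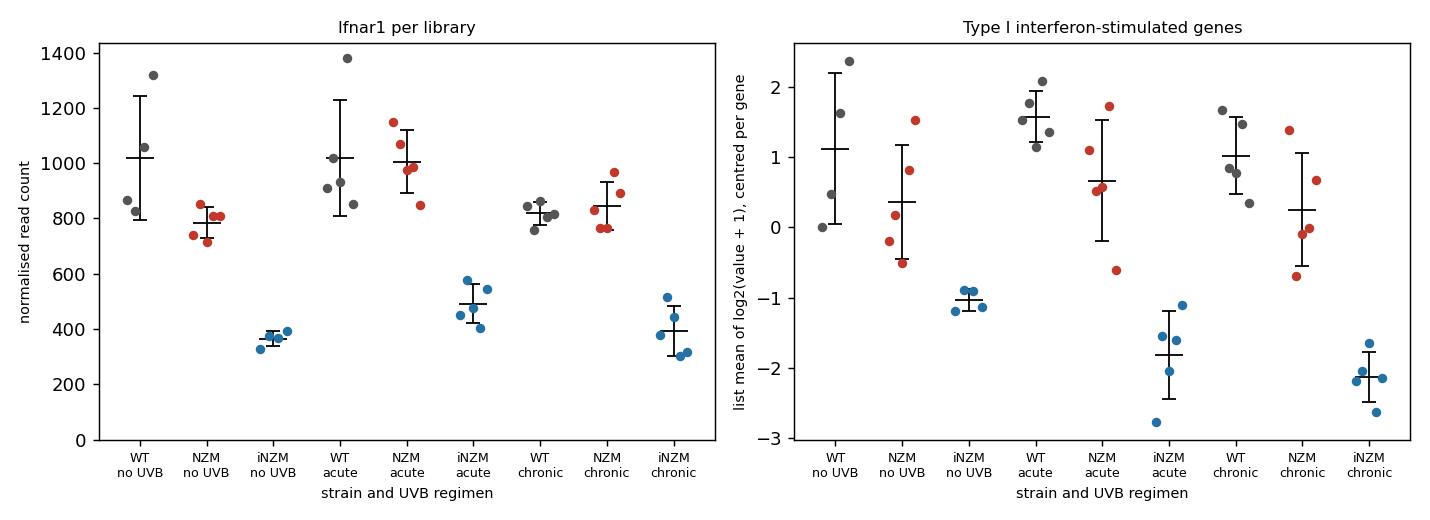
Normalised read count of Ifnar1 (left) and list mean of log2(value + 1), centred per gene, over the type I interferon-stimulated genes (right), for each strain and UVB regimen; each dot is a library and black bars give the mean ± SD. The iNZM libraries lie between 304 and 579 for Ifnar1, and their interferon-stimulated scores average -1.03 without UVB, -1.81 after acute and -2.13 after chronic UVB.

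The comparison of NZM skin after acute UVB with unexposed NZM skin asked what a single dose changed in the lupus-prone line. Saa3, an acute-phase protein gene, had a normalised read count of 2720 ± 2240 (SD, n = 5) after UVB and 12.2 ± 8.86 (n = 5) without, a log2 difference of 7.39 ± 0.87 (SE, limma adjusted p = 1.47e-07). The cytokine genes Il24 and Il6 had no reads in the unexposed libraries. Their means after UVB were at least 362-fold and at least 230-fold higher, against a floor of 3 reads over the group. Their log2 differences were 7.51 ± 0.89 and 6.59 ± 0.80. Of 31 keratinocyte stress and alarmin genes tested, 22 rose and 0 fell (22 and 1 adjusted over the list alone, camera adjusted p = 3.54e-14). That list had adjusted p = 0.187 with an estimated correlation. Among its members Lce3d rose by 6.61 ± 0.63, the wound keratin gene Krt6b by 5.43 ± 0.90 and the alarmin gene S100a8 by 4.75 ± 0.77 on the log2 scale. Neutrophil markers rose in 14 of 17 and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 1.75e-06, and adjusted p = 0.32 with an estimated correlation). Clec4e, a pattern receptor of myeloid cells, rose by 5.85 ± 1.02, while Il1r2, the decoy receptor for interleukin 1, fell by 2.65 ± 0.44. Ly6g, a neutrophil surface marker, stayed below the filter, with 0 in 35 of 43 libraries and at most 11 in any.

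Myeloid chemokines and inflammatory cytokines rose in 11 of 19 after acute UVB in NZM, and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 3.51e-07, and adjusted p = 0.32 with an estimated correlation). Cxcl5, a neutrophil-attracting chemokine gene, rose by 7.42 ± 1.12 on the log2 scale. Of 14 monocyte markers 9 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 0.000157, and adjusted p = 0.515 with an estimated correlation). Fcgr1, a high-affinity antibody receptor gene, rose by 3.01 ± 0.79, and Ly6c2, a marker of inflammatory monocytes, by 2.04 ± 0.64 (adjusted p = 0.0202, or 0.0624 without NZM acute UVB library 1). Tissue remodelling genes rose in 11 of 16 with 0 falling (12 and 0 adjusted over the list alone, camera adjusted p = 2.36e-09, and adjusted p = 0.187 with an estimated correlation). The protease gene Adamts4 rose by 5.92 ± 0.71. Targets of p53, the DNA damage regulator, rose in 12 of 26 and fell in 2 (13 and 4 adjusted over the list alone, camera adjusted p = 0.000333, and adjusted p = 0.32 with an estimated correlation). The death receptor gene Tnfrsf10b rose by 2.23 ± 0.26, and the repair gene Xpc fell by 0.90 ± 0.10.

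Epidermal differentiation genes fell in 11 of 22 after acute UVB in NZM and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 1.23e-06, and adjusted p = 0.479 with an estimated correlation). Lce1m, a cornified envelope gene, went from 48200 ± 10900 (n = 5) to 1810 ± 1600 (n = 5) normalised reads, and Krt10, a keratin gene of the upper epidermis, fell by 2.61 ± 0.72 on the log2 scale. Circadian clock genes fell in 7 of 13 with 0 rising (8 and 1 adjusted over the list alone, camera adjusted p = 0.000669, and adjusted p = 0.32 with an estimated correlation). Hlf fell by 2.37 ± 0.22 and Per1 by 1.45 ± 0.27. Gamma-delta T cell markers fell in 4 of 6 with 0 rising (5 and 0 adjusted over the list alone, camera adjusted p = 0.000157, and adjusted p = 0.187 with an estimated correlation). The receptor gene Trdc fell by 2.98 ± 0.57. Of 38 type I interferon-stimulated genes 0 rose and 2 fell (0 and 2 adjusted over the list alone), and camera gave adjusted p = 0.569. The hair follicle score was above 5 in 1 of the 5 libraries, NZM acute UVB 5. In all, limma called 4097 of 19170 genes, 2039 up and 2058 down.

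The same comparison in iNZM and in WT asked whether these responses were also present there. In iNZM, stress and alarmin genes rose in 20 of 31 and fell in 1 (20 and 2 adjusted over the list alone, camera adjusted p = 1.98e-06, and adjusted p = 0.367 with an estimated correlation). Neutrophil markers rose in 11 of 17 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000373, and adjusted p = 0.453 with an estimated correlation). Monocyte markers were called higher in 2 of 14 and lower in 0 (2 and 0 adjusted over the list alone), and camera gave adjusted p = 0.88, and adjusted p = 0.977 with an estimated correlation. Myeloid chemokines and inflammatory cytokines rose in 4 of 19 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.033, and adjusted p = 0.643 with an estimated correlation). That list call was lost without iNZM acute UVB 9 (0.127) or 10 (0.253), with fry (0.116) and when only these groups were fitted (0.0536). By score, chemokines differed by 1.44 (exact permutation p = 0.198, 0.347 adjusted) and monocyte markers by 0.21 (exact permutation p = 0.849, 0.886 adjusted) in iNZM, and in NZM by 2.86 (exact permutation p = 0.00794, 0.0371 adjusted) and 2.06 (exact permutation p = 0.0238, 0.08 adjusted). The iNZM libraries were split, with monocyte scores of 1.09 and 2.21 in 9 and 10 and -2.27, -1.33 and -0.94 in 6, 48 and 49. Tests within each strain do not test a difference between the strains. Neutrophil scores differed by 2.38 in iNZM (exact permutation p = 0.0317, 0.0918 adjusted) and 3.01 in NZM (0.00794, 0.0371 adjusted). Stress and alarmin scores differed by 2.11 in iNZM (exact permutation p = 0.0476, 0.108 adjusted) and 3.08 in NZM (0.00794, 0.0371 adjusted). Proliferation genes rose in 15 of 27 with 0 falling (23 and 0 adjusted over the list alone, camera adjusted p = 4.43e-07, and adjusted p = 0.52 with an estimated correlation). The DNA precursor gene Rrm2 rose by 1.83 ± 0.27. Differentiation genes fell in 16 of 22 with 0 rising (19 and 0 adjusted over the list alone, camera adjusted p = 2.89e-11, and adjusted p = 0.367 with an estimated correlation). Lce1m fell by 7.20 ± 0.77. Interferon gamma-induced and MHC class I genes fell in 14 of 21 with 0 rising (17 and 0 adjusted over the list alone, camera adjusted p = 1.21e-07, and adjusted p = 0.367 with an estimated correlation). The immunoproteasome gene Psmb9 fell by 1.85 ± 0.37. T cell markers fell in 11 of 17 with 0 rising (14 and 0 adjusted over the list alone, camera adjusted p = 3.47e-06, and adjusted p = 0.367 with an estimated correlation). Cd3g, part of the T cell receptor complex, fell by 3.29 ± 0.50. Hair follicle scores were above 5 in 2 of the 5 libraries, iNZM acute UVB 6 and 49. Limma called 4833 genes, 2451 up and 2382 down, and 3102 genes when only these groups were fitted. The balance depended on the method, with 1923 up and 2817 down after TMM scaling, 2958 and 2002 by edgeR and 3472 and 2279 by DESeq2.

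In WT after acute UVB, chemokine genes rose in 13 of 19 and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 4.41e-10, and adjusted p = 0.231 with an estimated correlation). Cxcl1, another neutrophil attractant gene, rose by 8.21 ± 0.75 and Cxcl5 by 10.08 ± 1.19, while Cxcl2, with no reads in the unexposed WT libraries, was at least 411-fold higher. Stress and alarmin genes rose in 21 of 31 and fell in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 9.17e-13, and adjusted p = 0.231 with an estimated correlation). Neutrophil markers rose in 13 of 17 and fell in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 2.6e-08, and adjusted p = 0.231 with an estimated correlation). Monocyte markers rose in 3 of 14 with 0 falling (3 and 0 adjusted over the list alone, camera adjusted p = 0.00175, and adjusted p = 0.623 with an estimated correlation). Their score differed by 1.74 (exact permutation p = 0.0317, 0.0918 adjusted), and the unexposed WT libraries stood apart, with -1.08 and -0.62 in 41 and 43 and 1.5 and 1.86 in 44 and 45. Targets of p53 rose in 14 of 26 and fell in 2 (18 and 2 adjusted over the list alone, camera adjusted p = 5.07e-09, and adjusted p = 0.105 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose by 1.73 ± 0.23. Limma called 4169 genes, 1996 up and 2173 down. Among genes called up after acute UVB, 1267 were shared by NZM and iNZM (260.7 expected if the calls were independent) and 1084 by NZM and WT (212.3 expected). Among those called down, 1366 were shared by NZM and iNZM (255.7 expected) and 1206 by NZM and WT (233.3 expected), each strain being set against its own unexposed libraries. The fit uses the same spread of a gene for all groups, so calls in different strains are not independent. An excess over the expected number therefore does not by itself measure a shared response.

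**Figure D2:**
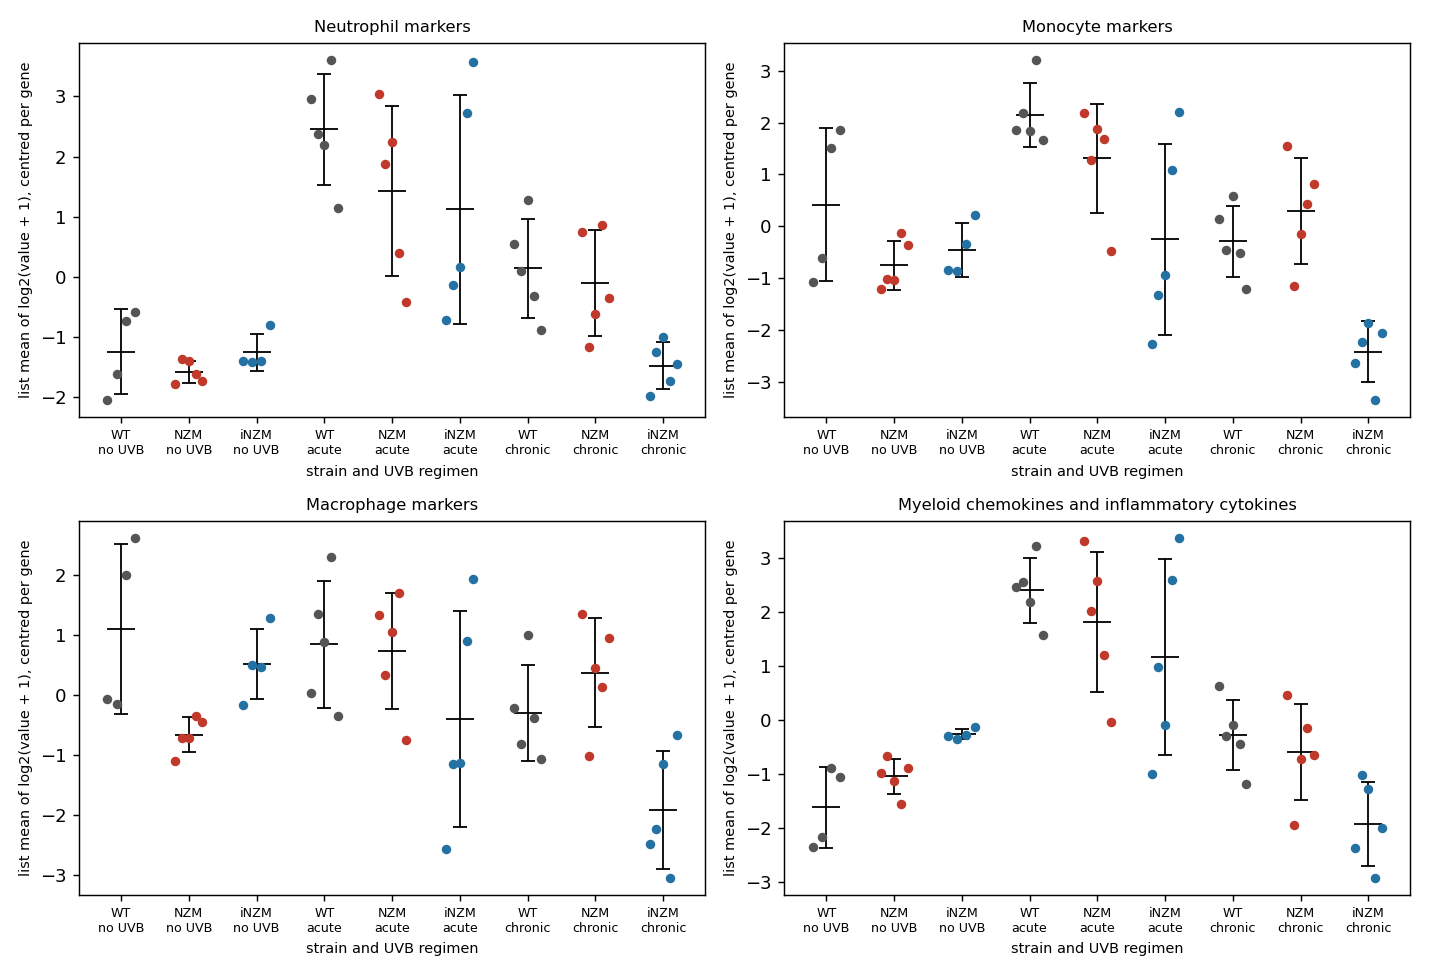
List mean of log2(value + 1), centred per gene, over neutrophil, monocyte and macrophage markers and over myeloid chemokines and inflammatory cytokines, for each strain and UVB regimen; each dot is a library and black bars give the mean ± SD. Neutrophil scores average 1.43 in NZM, 1.12 in iNZM and 2.45 in WT after acute UVB, and monocyte scores after chronic UVB average 0.30 in NZM, -2.43 in iNZM and -0.29 in WT.

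The comparison of chronic UVB with no UVB in NZM asked what 5 smaller daily doses left behind. Spink7, a protease inhibitor gene with no reads in unexposed NZM skin, rose by 7.40 ± 0.90 (SE, n = 5 and 5) on the log2 scale. Akr1d1, a steroid reductase gene, rose by 6.24 ± 0.75. Stress and alarmin genes rose in 12 of 31 with 0 falling (13 and 0 adjusted over the list alone, camera adjusted p = 1.17e-06, and adjusted p = 0.631 with an estimated correlation). Sprr1b, an envelope precursor gene, rose by 5.41 ± 0.88 and the gap junction gene Gjb6 by 2.68 ± 0.43. Basal keratinocyte genes fell in 9 of 10 with 0 rising (9 and 0 adjusted over the list alone, camera adjusted p = 4.66e-08, and adjusted p = 0.284 with an estimated correlation). Trp63, a regulator of basal cells, fell by 1.10 ± 0.17. Gamma-delta T cell markers fell in 5 of 6 with 0 rising (5 and 0 adjusted over the list alone, camera adjusted p = 3.18e-06, and adjusted p = 0.11 with an estimated correlation). Tcrg-V5, the receptor gene of the epidermal subset, fell by 4.50 ± 0.51. Interferon gamma-induced and MHC class I genes fell in 11 of 21 with 0 rising (16 and 0 adjusted over the list alone, camera adjusted p = 9.84e-08, and adjusted p = 0.631 with an estimated correlation). The GTPase gene Irgm1 fell by 1.77 ± 0.40. Hair follicle genes rose in 16 of 28 with 0 falling (23 and 0 adjusted over the list alone, camera adjusted p = 4.56e-08, and adjusted p = 0.631 with an estimated correlation). In 3 of the 5 libraries, NZM chronic UVB 17, 55 and 56, the hair follicle score was above 5. Krtap4-6, a hair keratin-associated gene with no reads in unexposed NZM skin, had 3430 ± 3940 (SD, n = 5) normalised reads. Its log2 difference was 8.90 ± 2.44 (limma adjusted p = 0.0114, or 0.154 without the libraries scoring above 5). Limma called 3638 genes, 1763 up and 1875 down. The count was 2155 without library 17, 2066 without 55, 1890 without 56, and 1006 without all 9 libraries scoring above 5, a choice made after seeing the data.

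In iNZM after chronic UVB, interferon gamma-induced and MHC class I genes fell in 21 of 21 (21 adjusted over the list alone, camera adjusted p = 9.04e-12, and adjusted p = 0.233 with an estimated correlation). MHC class II genes fell in 7 of 7 (7 adjusted over the list alone, camera adjusted p = 4.4e-08, and adjusted p = 0.231 with an estimated correlation). H2-Ab1, an MHC class II chain gene, went from 10500 ± 1600 (SD, n = 4) to 1310 ± 611 (n = 5) normalised reads. Dendritic cell markers fell in 12 of 16 with 0 rising (14 and 0 adjusted over the list alone, camera adjusted p = 4.4e-08, and adjusted p = 0.231 with an estimated correlation). The Langerhans cell gene Cd207 fell by 3.05 ± 0.53, and the chemokine gene Ccl22 fell by 4.05 ± 0.62. Macrophage markers fell in 12 of 15 with 0 rising (13 and 1 adjusted over the list alone, camera adjusted p = 4.35e-05, and adjusted p = 0.324 with an estimated correlation). Lyve1 fell by 3.57 ± 0.84. Monocyte markers fell in 8 of 14 with 0 rising (10 and 0 adjusted over the list alone, camera adjusted p = 0.000607, and adjusted p = 0.324 with an estimated correlation). The coagulation factor gene F10 fell by 4.60 ± 0.83. Fibroblast and matrix genes fell in 14 of 18 with 0 rising (16 and 0 adjusted over the list alone, camera adjusted p = 6.09e-06, and adjusted p = 0.324 with an estimated correlation). Type I interferon-stimulated genes fell in 14 of 38 and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 5.22e-05, and adjusted p = 0.379 with an estimated correlation). Hair follicle genes rose in 20 of 28 with 0 falling (26 and 0 adjusted over the list alone, camera adjusted p = 4.4e-08, and adjusted p = 0.324 with an estimated correlation). Their score was above 5 in iNZM chronic UVB 22, 24 and 25. Camera called 28 of the 36 lists in this comparison, 24 of them lower, so a fall was not particular to the lists named. Limma called 5533 genes, 2520 up and 3013 down. TMM scaling gave 1914 up and 3652 down, while edgeR gave 2882 and 2373 and DESeq2 3381 and 2663, which turns the majority. The count was 3359 without chronic UVB library 24, 3680 and 3647 without the unexposed libraries 39 and 40, 2397 with the hair follicle score as a covariate, and 3003 when only these groups were fitted.

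In WT after chronic UVB, stress and alarmin genes rose in 25 of 31 with 0 falling (25 and 0 adjusted over the list alone, camera adjusted p = 8.07e-15, and adjusted p = 0.395 with an estimated correlation). Krt16, a keratin gene of activated epidermis, rose by 6.67 ± 0.76. Stfa3, a protease inhibitor gene, went from 48.5 ± 32.6 (SD, n = 4) to 41700 ± 7790 (n = 5) normalised reads. Proliferation genes rose in 23 of 27 with 0 falling (24 and 0 adjusted over the list alone, camera adjusted p = 6.53e-10, and adjusted p = 0.917 with an estimated correlation). Birc5, needed for cell division, rose by 2.83 ± 0.40. Differentiation genes rose in 9 of 22 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000874, and adjusted p = 0.917 with an estimated correlation). Flg, which encodes the barrier protein filaggrin, rose by 6.60 ± 0.79. Adipocyte genes fell in 12 of 15 with 0 rising (13 and 0 adjusted over the list alone, camera adjusted p = 0.000178, and adjusted p = 0.917 with an estimated correlation). The hormone gene Lep fell by 2.99 ± 0.80. Limma called 6761 genes, 3532 up and 3229 down. NZM and WT shared 851 genes called up after chronic UVB (324.8 expected if independent) and 1058 called down (315.8 expected), while NZM and iNZM shared 1045 up (231.8 expected) and 1202 down (294.7 expected). As for acute UVB, the calls are not independent, because the fit uses the same spread of a gene for all groups.

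**Figure D3:**
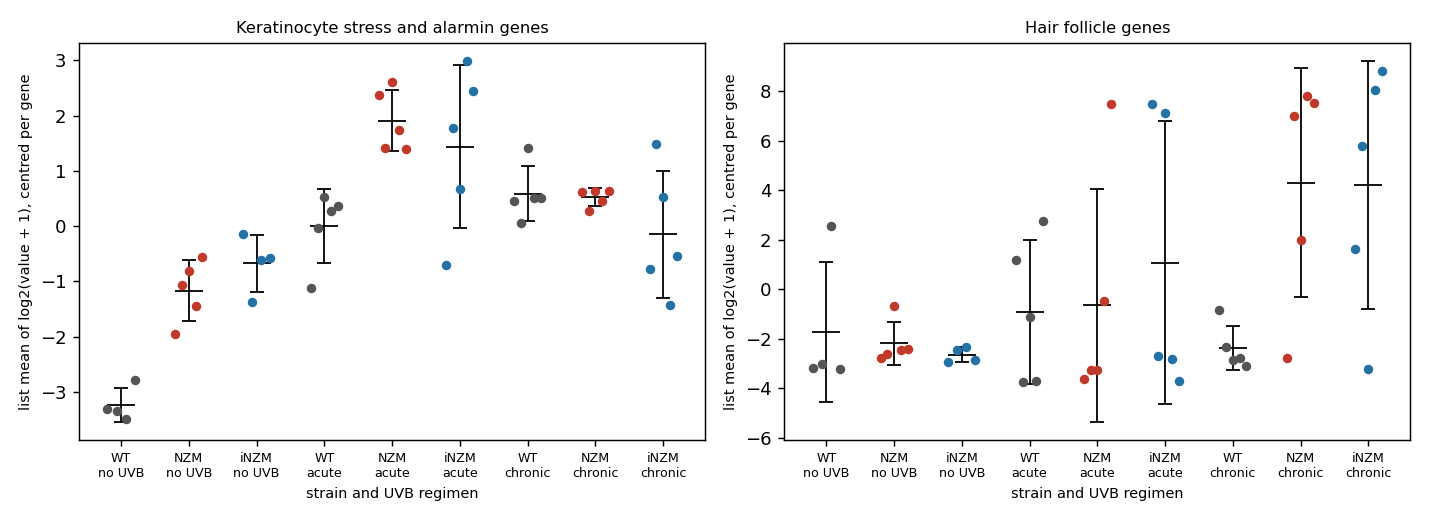
List mean of log2(value + 1), centred per gene, over keratinocyte stress and alarmin genes (left) and hair follicle genes (right), for each strain and UVB regimen; each dot is a library and black bars give the mean ± SD. Stress scores average -3.23 in WT and -1.17 in NZM without UVB, and hair follicle scores are above 5 in 9 libraries, all NZM or iNZM after UVB.

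NZM and WT were compared within each regimen to ask how the lupus-prone line differed from the control. Without UVB, 3 Skint genes, members of a family expressed by epidermal cells, had no reads in WT. Skint3 was at least 5470-fold, Skint9 at least 4770-fold and Skint4 at least 3560-fold higher in NZM (n = 5) than in WT (n = 4). Their log2 differences were 11.84 ± 0.46, 11.68 ± 0.55 and 11.29 ± 0.33. These genes also had no reads in WT after acute or chronic UVB, and lie together on chromosome 4 (112072016 to 112433985). Whether the WT strain carries them in a form that reads can be mapped to was not tested. Stress and alarmin genes were higher in 14 of 31 with 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 2.32e-09, and adjusted p = 0.729 with an estimated correlation). Il1f6, an interleukin 1 family cytokine gene, differed by 4.66 ± 0.84. Adipocyte genes were lower in 12 of 15 with 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 1.64e-09, and adjusted p = 0.729 with an estimated correlation). Plin1, a coat protein gene of fat droplets, had 672 ± 347 normalised reads in NZM and 8170 ± 3310 in WT. Fibroblast and matrix genes were lower in 13 of 18 and higher in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 2.37e-07, and adjusted p = 0.729 with an estimated correlation). The collagen gene Col1a2 differed by -2.71 ± 0.63. Type I interferon-stimulated genes were lower in 5 of 38 with 0 higher (5 and 0 adjusted over the list alone, camera adjusted p = 0.00797, and adjusted p = 0.857 with an estimated correlation). Ifi44l differed by -6.11 ± 0.55, and was near 0 in NZM under every regimen (means of 1.16 without UVB, and 0 after acute and chronic UVB). By score, the interferon-stimulated list differed by -0.75 (exact permutation p = 0.27, 0.428 adjusted). That list call was lost without NZM library 33 (0.0691) and without WT library 45 (0.245). The 4 WT libraries formed 2 pairs. The chi-square per gene was 44.6 between 41 and 43 and 49.7 between 44 and 45, and 139.4 to 230.2 across the pairs. The 10 most abundant genes took 14.3% and 12.51% of reads in 41 and 43, and 7.2% and 7.6% in 44 and 45. Macrophage scores were -0.07 and -0.14 in 41 and 43 and 2.01 and 2.62 in 44 and 45, and matrix scores 0.14 and 0.49 against 1.63 and 2. The NZM libraries lay below every WT library on both, from -1.09 to -0.34 and from -1.22 to -0.05. Macrophage scores differed between NZM and WT by -1.77 (exact permutation p = 0.00794, 0.0371 adjusted). Interferon-stimulated scores were 0.01 and 0.47 against 1.63 and 2.36, where NZM libraries ran from -0.5 to 1.52. Adipocyte scores were between 1.3 and 2.12 in all 4, above the NZM libraries, which reached 0.14. Limma called 2868 genes, 1432 higher and 1436 lower in NZM, or 1662 without WT library 45.

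After acute UVB, proliferation genes were higher in NZM than in WT in 20 of 27 with 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 1.74e-11, and adjusted p = 0.773 with an estimated correlation). Birc5 differed by 1.93 ± 0.38. Differentiation genes were higher in 13 of 22 with 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 1.06e-07, and adjusted p = 0.773 with an estimated correlation). Rptn, an envelope protein gene, differed by 5.90 ± 0.79. Targets of p53 were lower in 7 of 26 with 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 0.000152, and adjusted p = 0.773 with an estimated correlation). Aen, a nuclease gene, differed by -0.82 ± 0.16. Type I interferon-stimulated genes were lower in 3 of 38 with 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 2.47e-05, and adjusted p = 0.876 with an estimated correlation). By score, that list differed by -0.92 (exact permutation p = 0.0476, 0.108 adjusted). Ifi44l, near 0 in NZM under every regimen, was among the members called. Limma called 2499 genes, 1525 higher and 974 lower in NZM. After chronic UVB, hair follicle genes were higher in 12 of 28 with 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 5.73e-11, and adjusted p = 0.969 with an estimated correlation). The NZM libraries 17, 55 and 56 carried the high scores. Interferon-stimulated genes were lower in 5 of 38 with 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 0.000238, and adjusted p = 0.969 with an estimated correlation). That call was lost with the hair follicle score as a covariate (0.278). By score, interferon-stimulated genes differed by -0.77 after chronic UVB (exact permutation p = 0.127, 0.248 adjusted), and Ifi44l was again among the members called. Limma called 1511 genes after chronic UVB, 822 higher and 689 lower, or 737 higher and 941 lower with quantile normalization. That count was 995 without NZM library 56 and 2532 with the hair follicle covariate.

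iNZM and NZM were compared within each regimen to ask what differed in the line with lower Ifnar1. After acute UVB, 19 of 38 type I interferon-stimulated genes were lower in iNZM and 0 higher (34 and 0 adjusted over the list alone, camera adjusted p = 1.19e-82), and the call held with adjusted p = 0.000433 with an estimated correlation. Rsad2, an antiviral enzyme gene, had 11.9 ± 9.54 normalised reads (SD, n = 5) in iNZM and 186 ± 106 (n = 5) in NZM, a log2 difference of -3.93 ± 0.52 (limma adjusted p = 1.52e-05). Oas1a, which encodes a sensor enzyme for viral RNA, differed by -4.32 ± 0.64, and the monocyte marker Ly6c2 by -3.74 ± 0.64 (9.50 ± 9.95 against 103 ± 48.5 reads). Interferon gamma-induced and MHC class I genes were lower in 3 of 21 with 0 higher (10 and 0 adjusted over the list alone, camera adjusted p = 2.86e-23, and adjusted p = 0.0682 with an estimated correlation). Camera called 31 of the 36 lists in this comparison, 27 of them lower in iNZM. Monocyte markers were lower in 1 of 14 with 0 higher (5 and 0 adjusted over the list alone, camera adjusted p = 3.9e-09, and adjusted p = 0.245 with an estimated correlation). The iNZM libraries 6 and 49 had hair follicle scores of 7.49 and 7.13 and monocyte scores of -2.27 and -0.94. Library 48 had -2.71 and -1.33, while 9 and 10 had monocyte scores of 1.09 and 2.21. Without the libraries with hair follicle scores above 5, a choice made after seeing the data, 7 lists changed sign in this comparison. Of these only stress and alarmin genes were called in the new direction (0.00953), and the others lost their call. Monocyte markers kept their direction and call (0.000193). Of the stress genes fixed in advance, S100a8 differed by -0.06 ± 0.77 and Krt6b by -1.04 ± 0.90, with adjusted p of 0.997 and 0.96. Limma called 43 genes, 1 higher and 42 lower, with 735 at an unadjusted p below 0.05; edgeR called 32 and DESeq2 64. The gene called higher, RP23-421P23.7, was singled out after its values were seen. The count was 26, 28 and 21 without NZM acute UVB 1, 46 and 47, and 26 without iNZM acute UVB 49. When only these groups were fitted, 1 gene was called, and Rsad2 (adjusted p = 0.114), Oas1a (0.11) and Ly6c2 (0.454) lost the call.

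After chronic UVB, 18 of 38 interferon-stimulated genes were lower in iNZM than in NZM and 0 higher (30 and 0 adjusted over the list alone, camera adjusted p = 4.28e-50, and adjusted p = 0.0126 with an estimated correlation). Oas1a differed by -4.42 ± 0.64 and Oasl2, of the same antiviral family, by -4.26 ± 0.57 (a mean of 16 ± 7.87 reads, n = 5, against 370 ± 289, n = 5). Monocyte markers were lower in 4 of 14 with 0 higher (11 and 0 adjusted over the list alone, camera adjusted p = 3.95e-17, and adjusted p = 0.0328 with an estimated correlation). Ly6c2 had 2.22 ± 2.05 reads in iNZM and 91.3 ± 95.2 in NZM (log2 difference -4.54 ± 0.64, limma adjusted p = 6.53e-05). Camera called 27 of the 36 lists here, 24 of them lower in iNZM, and the stromal score, a mean over the fibroblast, endothelial and adipocyte lists, also differed by -1.29 (exact permutation p = 0.0317). Macrophage markers were lower in 1 of 15 with 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 5.2e-15, and adjusted p = 0.0704 with an estimated correlation). Neutrophil markers were lower in 1 of 17 with 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 4.08e-05, and adjusted p = 0.211 with an estimated correlation). That member, the growth factor receptor gene Csf3r, differed by -4.27 ± 0.81 (limma adjusted p = 0.00553). It lost the call when only these groups were fitted (0.0676) and without the libraries scoring above 5 (0.054). Mast cell markers were lower in 0 of 9 (8 adjusted over the list alone, camera adjusted p = 9.7e-11, and adjusted p = 0.0328 with an estimated correlation). Interferon ligands and receptors were lower in 1 of 5 (2 adjusted over the list alone, camera adjusted p = 0.000112, and adjusted p = 0.0155 with an estimated correlation). The member called was Ifnar1, so this list partly restates the receptor difference between the strains. Of its 14 members 9 were not tested, and these were all ligand genes (Ifnb1, Ifnk, Ifne, Ifna2, Ifna4, Ifna5, Ifng, Ifnl2 and Ifnl3). The list call therefore gives no information on those ligands. Over the 17 comparisons, these 4 lists after chronic UVB and the interferon-stimulated list after acute UVB were the only list calls that held with an estimated correlation. Limma called 82 genes, 3 higher and 79 lower; edgeR called 48 and DESeq2 222. The 3 called higher, RP24-168F5.2, RP23-265P8.4 and Mir124-2hg, were singled out after their values were seen.

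That count of 82 moved with single libraries. It was 20, 162, 51 and 30 without NZM chronic UVB 54, 17, 18 and 56, and 35, 319, 29 and 208 without iNZM chronic UVB 57, 23, 24 and 25. It was 453 with the hair follicle score as a covariate, 26 without the libraries scoring above 5, and 4 when only these groups were fitted, where Oas1a (0.0676) and Ly6c2 (0.0706) lost the call. Oas1a also lost it without the libraries scoring above 5 (0.0555). Without UVB, 4 of 38 interferon-stimulated genes were lower in iNZM and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 3.67e-28, and adjusted p = 0.162 with an estimated correlation). Ifi44 differed by -4.62 ± 0.75 (limma adjusted p = 0.0024, or 0.0626 without iNZM library 40, 0.0545 with a pseudocount of 8 and 0.101 when only these groups were fitted). Over the 36 lists, camera called 16 higher and 3 lower in iNZM without UVB, and 0 of them held with an estimated correlation. Macrophage markers were among those higher, with 0 of 15 members called (0 adjusted over the list alone, camera adjusted p = 8.65e-06, and adjusted p = 0.423 with an estimated correlation). Limma called 6 genes without UVB, 0 higher and 6 lower, with 1082 at an unadjusted p below 0.05, against 5 by edgeR and 81 by DESeq2. The direction turned when only these groups were fitted (10 higher and 6 lower) and with sample quality weights (145 and 129). The count was 3 without NZM library 34, 3 without iNZM library 37, 3 without 39 and 2 without 40. Interferon-stimulated scores differed between iNZM and NZM by -1.39 without UVB (exact permutation p = 0.0159, 0.0556 after Benjamini-Hochberg adjustment over 84 score tests). They differed by -2.47 after acute and -2.38 after chronic UVB (exact permutation p = 0.00794 for each, the smallest the test can give, 0.0371 adjusted). Monocyte scores differed by -2.72 after chronic UVB (exact permutation p = 0.00794, 0.0371 adjusted) and by -1.56 after acute UVB (exact permutation p = 0.127, 0.248 adjusted). Macrophage scores were higher in iNZM by 1.18 without UVB (exact permutation p = 0.00794, 0.0371 adjusted) and differed by -2.28 after chronic UVB (exact permutation p = 0.0159, 0.0556 adjusted). Neutrophil scores differed by -0.31 after acute UVB (exact permutation p = 0.81) and -1.37 after chronic UVB (exact permutation p = 0.0159, 0.0556 adjusted).

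Differences between strains in the UVB response itself were tested as interactions. For acute UVB, the response of NZM differed from that of WT in 22 genes, 10 with a higher and 12 with a lower value, with 1947 at an unadjusted p below 0.05, and edgeR called 9 and DESeq2 207. Nfkbiz, a regulator of inflammatory transcription, differed by -2.59 ± 0.45 (SE, limma adjusted p = 0.00441) and Hsd17b14, a steroid dehydrogenase gene, by 2.43 ± 0.38 (0.000844). Cxcl1 differed by -4.14 ± 1.03 (0.0894) and Cxcl2 by -5.14 ± 1.34 (0.115). The acute count was 41 without WT acute UVB 52 and 13 without WT library 45. For chronic UVB, 1454 genes differed between NZM and WT, 671 higher and 783 lower. Quantile normalization gave 568 higher and 981 lower, TMM scaling 719 and 664, edgeR 899 and 775 and DESeq2 1339 and 1191. Stress and alarmin genes had a lower value in 9 of 31 with 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 6.07e-08, and adjusted p = 0.638 with an estimated correlation). Their scores were alike after chronic UVB, 0.52 in NZM and 0.58 in WT (exact permutation p = 0.841). Without UVB they were -1.17 in NZM and -3.23 in WT (exact permutation p = 0.00794), so this interaction reflects the unexposed levels. Stfa3 differed by -5.77 ± 1.00. Fibroblast and matrix genes had a higher value in 12 of 18 and a lower in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 1.05e-07, and adjusted p = 0.638 with an estimated correlation). The proteoglycan gene Dcn differed by 2.91 ± 0.70. The unexposed WT libraries were split on this list, with scores of 0.14 and 0.49 in 41 and 43 and 1.63 and 2 in 44 and 45. The chronic count was 928 and 894 without NZM chronic UVB 55 and 56, 892 without WT chronic UVB 29, 933 without NZM library 34, 608 without WT library 45, and 4082 with the hair follicle covariate.

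Between iNZM and NZM, the acute response differed in 1 gene, RP24-208K8.1, by 5.10 on the log2 scale (adjusted p = 0.0165), with 1215 genes at an unadjusted p below 0.05. This gene, singled out after its values were seen, left a count of 0 by limma without any of 9 libraries: NZM acute UVB 1, 5 and 47, iNZM acute UVB 48 and 49, NZM without UVB 34, and iNZM without UVB 37, 38 and 40. The acute count was 0 by edgeR and 5 by DESeq2. For chronic UVB, limma called 0 genes, with 2134 at an unadjusted p below 0.05, while edgeR called 0 and DESeq2 379. The limma count was 178 and 1 without NZM chronic UVB 17 and 55, 267 and 210 without iNZM chronic UVB 23 and 25, 10 without NZM library 33, and 467 with the hair follicle covariate. In simulated data of this size, the test of the chronic interaction recovered 59.6% of genes changed 4-fold and 20.4% of those changed 2-fold. Genes were drawn independently there, without the split of the real libraries by hair follicle score. These rates therefore do not describe the real comparison.

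Chronic and acute UVB were compared as a mean over the 3 strains. Differentiation genes were higher after chronic UVB in 22 of 22 (22 adjusted over the list alone, camera adjusted p = 1.37e-16, and adjusted p = 0.355 with an estimated correlation). Flg differed by 5.69 ± 0.43 and Krt10 by 3.11 ± 0.42. Chemokine and cytokine genes were lower in 16 of 19 and higher in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 3.57e-09, and adjusted p = 0.452 with an estimated correlation). Cxcl5 differed by -6.62 ± 0.65. Neutrophil markers were lower in 15 of 17 and higher in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 5.69e-06, and adjusted p = 0.479 with an estimated correlation). Trem1, an amplifier of myeloid activation, differed by -3.44 ± 0.54. Monocyte markers were lower in 13 of 14 with 0 higher (14 and 0 adjusted over the list alone, camera adjusted p = 6.32e-06, and adjusted p = 0.489 with an estimated correlation). Limma called 8545 genes, 4336 higher and 4209 lower after chronic UVB.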

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

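The tests of library number against hair follicle score, of the growth phase, of UVB itself, of hair follicle growth and dermal share behind the myeloid difference, and of hair follicle growth behind the chronic response were chosen only after the result was seen. The covariate for the library number behind the chronic response was chosen before.

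Hair follicle genes were very high in 9 libraries, all NZM or iNZM after UVB, with scores above 5. A batch of libraries numbered 46 or above is argued against, because 6 of the 9 had numbers below 46, and 13 of the 30 UVB libraries had numbers of 46 or above (Fisher's exact p = 0.87). Follicles in the growth phase of the hair cycle remain a possible explanation, since hair follicle and melanocyte scores rose together in the 34 other libraries (Spearman rho = 0.75). UVB itself cannot be told apart here, because the test within NZM and iNZM (scores higher by 4.02 and 5.29, exact permutation p = 0.0159) restates how the pattern was seen, and in WT, outside the pattern, the difference was 0.07 (exact permutation p = 0.949). No animal's hair cycle stage is in the labels.

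Monocyte and macrophage markers were lower in iNZM than in NZM after chronic UVB, with a median log2 difference of -2.69 over 29 genes. Hair follicle growth in these libraries is argued against as the whole source, because hair follicle scores averaged 4.21 in iNZM and 4.31 in NZM (exact permutation p = 0.96). With scores so alike, that score as a covariate could hardly move the median, which was then -2.71. A lower share of dermal tissue in the biopsies is argued against too, because the myeloid score minus the stromal score differed by -1.21 between iNZM and NZM (exact permutation p = 0.00794). The stromal score itself differed by -1.29 (exact permutation p = 0.0317), so a smaller dermal share may account for part of the pattern. No biological explanation was tested.

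The chronic UVB response differed between NZM and WT in 1454 genes. Hair follicle growth in the NZM libraries is argued against as the whole source, because with the hair follicle score as a covariate 1261 of these genes kept their call and direction, with a median 0.993 of their log2 difference (quartiles 0.821 and 1.14). Without the 9 libraries, so with fewer, 905 of them kept it, with a median of 0.937, and some genes did move, as melanocyte genes reversed under each of these settings. The 1454 genes were chosen by the fit without the covariate. In that fit a gene that follows the hair follicle score varies widely within groups and is called less easily. Both results therefore cover these 1454 genes only. A batch of libraries numbered 46 or above is argued against, because with a covariate for the number 1427 genes differed and 1373 of the 1454 kept their call and direction. The strain background stays open and untested, as does the split of the unexposed WT libraries into pairs, with 608 genes without WT library 45.

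Single libraries that lay far from the rest of their group, by Dixon's test, were found in 6 of 81 groups of values, where chance marks about 1 in 20. The neutrophil score of iNZM without UVB 40 was -0.8 (nearest -1.4). Hair follicle scores were 7.47 in NZM acute UVB 5 (nearest -0.49), -0.66 in NZM without UVB 33 (nearest -2.43) and 2.54 in WT without UVB 44 (nearest -3.01). Depth was 37.76 M reads in NZM chronic UVB 56 (nearest 27.03) and 31.28 M in iNZM without UVB 39 (nearest 25.63).

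The other results marked here are differences between strains in the UVB response, tested as interactions, each given as a median log2 difference over the list, with the camera adjusted p and the adjusted p with an estimated correlation. For acute UVB in NZM against WT, 22 genes differed, macrophage markers by 2.04 (0.000154, 0.87) and chemokines and cytokines by -1.01 (0.0123, 0.87). For chronic UVB in NZM against WT, monocyte markers differed by 2.26 (0.00385, 0.693), macrophage markers by 3.05 (1.94e-05, 0.638), stress and alarmin genes by -1.97 (6.07e-08, 0.638) and hair follicle genes by 7.6 (1.69e-07, 0.668). The unexposed WT libraries behind these values stood apart in pairs, with macrophage scores of 2.01 and 2.62 in 44 and 45 and -0.07 and -0.14 in 41 and 43, and monocyte scores of 1.5 and 1.86 against -1.08 and -0.62. Stress and alarmin scores differed between NZM and WT without UVB (-1.17 and -3.23) and were alike after chronic UVB (0.52 and 0.58).

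For acute UVB in iNZM against NZM, 1 gene differed, and camera called 29 of the 36 lists, 25 of them lower. Interferon-stimulated genes differed by -1.02 (6.19e-08, 0.257), monocyte markers by -2.14 (6.23e-07, 0.242), macrophage markers by -2.74 (2.38e-09, 0.216) and chemokines and cytokines by -1.47 (1.65e-05, 0.257). Stress and alarmin genes differed by -0.93 (0.000142, 0.333) and hair follicle genes by 2.27 (0.00271, 0.557). For chronic UVB in iNZM against NZM, where camera called 25 of the 36 lists, 23 of them lower, interferon-stimulated genes differed by -0.82 (8.38e-05, 0.406), neutrophil markers by -1.4 (0.000518, 0.305) and monocyte markers by -3.34 (1.63e-11, 0.0787). Macrophage markers differed by -4.14 (5.78e-15, 0.0607), chemokines and cytokines by -2.16 (3.52e-07, 0.201) and stress and alarmin genes by -1.05 (8.38e-05, 0.326). In each interaction of this paragraph the adjusted p with an estimated correlation was above 0.05.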

How the results depend on the processing

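The hair follicle covariate and the runs without the 9 libraries scoring above 5 were chosen only after the result was seen, and the other settings before. A list is said to reverse where its sign changed and it was called in the main test, in the other setting or in both. The adjusted p beside it belongs to the new sign, and where that is above 0.05 the list only lost its call. Of 332 list calls, 242 held whichever library was left out, and of 316 calls of named genes 256 held. Outside the runs without a library, list tests kept their side of the threshold 6937 times, lost the call 755 times, gained it 200 times and reversed 30 times. The 6937 include lists not called in the main test. Most losses came from the choice of list test, as 327 of the 332 calls were lost with an estimated correlation and 198 with fry. Depth, from 18.49 M reads up, bounds what can be seen of genes with few reads, such as Ly6g with at most 11. Groups of 4 or 5 bound it further. In simulated data with genes drawn independently, the test of iNZM against NZM without UVB recovered 38.8% of genes changed 2-fold. No paired analysis was possible because the sample numbers tie no library to another. Where a value moved, the cause was not tested, unless fewer libraries or genes or a stricter threshold make it plain.

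At an adjusted p below 0.01, a stricter threshold by construction, limma called 2343, 2704 and 2631 genes for acute UVB in NZM, iNZM and WT. It called 1278, 2270 and 4212 for chronic UVB in the same order, and 1510, 1410 and 787 for NZM against WT without UVB, after acute and after chronic UVB. For iNZM against NZM the counts were 3, 23 and 27. For the response of NZM against WT they were 8 for acute and 290 for chronic UVB, and for the acute response of iNZM against NZM 0.

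With the correlation estimated, the camera adjusted p of interferon-stimulated genes in iNZM against NZM was 0.162 without UVB. Monocyte markers had 0.245 after acute UVB and neutrophil markers 0.211 after chronic UVB. In the chronic response of NZM against WT monocyte markers had 0.693. In the acute response of iNZM against NZM interferon-stimulated genes had 0.257 and monocyte markers 0.242, and in the chronic response interferon-stimulated genes had 0.406, neutrophil markers 0.305 and monocyte markers 0.0787. With fry the same results, apart from the last, had 0.146, 0.216, 0.0871, 0.212, 0.22, 0.184, 0.265 and 0.152.

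With a pseudocount of 8, 36 genes differed between iNZM and NZM after chronic UVB and 70 in the acute response of NZM against WT, where neutrophil markers gained a call (0.0191). With the filter at 50, which tests fewer genes, the acute response of iNZM against NZM gave 0 genes, and neutrophil markers gained a call there (0.0353). Quantile normalization reversed ribosomal protein genes after acute UVB in iNZM (adjusted p = 0.279), after chronic UVB in NZM (0.0545) and in the acute response of NZM against WT (0.287). EdgeR called 48 genes for iNZM against NZM after chronic UVB, 9 for the acute response of NZM against WT and 0 for the acute response of iNZM against NZM. DESeq2 called 81 genes for iNZM against NZM without UVB and 222 after chronic UVB, 207 and 2530 for the acute and chronic responses of NZM against WT, and 5 and 379 for those of iNZM against NZM. The larger direction was not stable in most comparisons, and only some of the turns are given here. It turned with edgeR and DESeq2 for acute UVB in NZM (2304 up and 1957 down, 2673 and 2317), chronic UVB in NZM (1888 and 1658, 2332 and 2078) and the acute response of NZM against WT (6 and 3, 143 and 64). It turned with edgeR and quantile normalization for acute UVB in WT (2030 and 1986, 2192 and 1989) and chronic against acute UVB (4004 and 4390, 3969 and 4510), and with TMM scaling for the latter (4188 and 4334) and for chronic UVB in WT (3187 and 3499). EdgeR and DESeq2 also turned it for chronic UVB in iNZM (2882 and 2373, 3381 and 2663) and the chronic response of NZM against WT (899 and 775, 1339 and 1191).

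With only the compared groups in the fit, so with fewer libraries, 3102 genes were called for acute and 3003 for chronic UVB in iNZM. For iNZM against NZM 16, 1 and 4 genes were called without UVB, after acute and after chronic UVB, and monocyte markers gained a call without UVB (0.015). The responses of NZM against WT gave 50 genes for acute and 2187 for chronic UVB, and those of iNZM against NZM gave 0 and 391. With sample quality weights, 7784 genes were called for acute UVB in NZM, 6347 for chronic UVB in NZM and 10162 in iNZM. NZM against WT gave 4457, 5843 and 2823, and iNZM against NZM gave 274 without and 628 after chronic UVB. The responses of NZM against WT gave 274 and 3088, and those of iNZM against NZM 0 and 1230. Quality weights reversed 3 lists in iNZM against NZM after chronic UVB: proliferation (0.0118), stress and alarmin (0.0546) and differentiation genes (0.684).

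With the hair follicle score as a covariate, 2397 genes were called for chronic UVB in iNZM and 2532 for NZM against WT after chronic UVB. For iNZM against NZM 17 were called without and 453 after chronic UVB, 86 and 4082 for the responses of NZM against WT, and 467 for the chronic response of iNZM against NZM. This covariate reversed T cell (0.894), proliferation (0.894) and melanocyte genes (0.894) for chronic UVB in NZM. In NZM against WT after chronic UVB it reversed interferon gamma-induced and MHC class I (0.382), muscle (0.000113), endothelial (0.0181) and melanocyte genes (9.88e-12), and in the chronic response of NZM against WT melanocyte genes (0.000654).

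Without the 9 libraries scoring above 5, 1006 genes were called for chronic UVB in NZM and 4342 for NZM against WT without UVB. For iNZM against NZM 17, 27 and 26 were called, for the acute response of NZM against WT 79, and for the responses of iNZM against NZM 0 and 4. Hair follicle genes reversed after acute UVB in iNZM (0.534), in NZM against WT after acute UVB (0.0129), and in the acute response of NZM against WT (0.0295). Muscle genes reversed after chronic UVB in iNZM (0.896), in NZM against WT after chronic UVB (2.22e-06), and in the acute (0.667) and chronic (0.0112) responses of iNZM against NZM. Melanocyte genes reversed in NZM against WT after chronic UVB (2.3e-07) and in the chronic response of NZM against WT (0.0483). In iNZM against NZM after acute UVB, MHC class II (0.519), chemokine (0.853), T cell (0.847), stress and alarmin (0.00953), hair follicle (0.483), muscle (0.235) and remodelling genes (0.853) reversed.

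Leaving out 1 library at a time gave counts from 1890 to 4307 for chronic UVB in NZM and 3359 to 6477 in iNZM. For NZM against WT the counts ran from 1662 to 2743 without UVB and 995 to 1755 after chronic UVB. For iNZM against NZM they ran from 2 to 8 without UVB, 21 to 60 after acute and 20 to 319 after chronic UVB. The responses of NZM against WT ran from 13 to 41 for acute and 608 to 1719 for chronic UVB, and those of iNZM against NZM from 0 to 1 and 0 to 267. The camera adjusted p of neutrophil markers ran from 0.00555 to 0.894 in iNZM against NZM after acute UVB, 0.00946 to 0.49 in the acute response of NZM against WT and 0.00785 to 0.704 in that of iNZM against NZM. It ran from 0.000321 to 0.948 for interferon-stimulated genes in the acute response of NZM against WT, and from 0.0445 to 0.642 for monocyte markers in iNZM against NZM without UVB. In iNZM against NZM, stress and alarmin genes reversed after acute UVB without iNZM 6 (0.577, the highest adjusted p of these runs, with 1.02e-05 the lowest). After chronic UVB, hair follicle genes reversed without NZM 54 (0.00903, range 0.00109 to 0.851). Without iNZM 57, proliferation genes (0.00673) and muscle genes (0.0372, range 0.0183 to 0.857) reversed.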

Other observations

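Skeletal muscle genes, from the muscle layer under the skin, fell after chronic UVB in 13 of 17 in NZM with 0 rising (15 and 0 adjusted over the list alone, camera adjusted p = 1.16e-06, and adjusted p = 0.631 with an estimated correlation). Of the 5 NZM libraries 3 had hair follicle scores above 5, and the muscle gene Myh2 lost its call with the hair follicle covariate (adjusted p = 0.168) and without the libraries scoring above 5 (0.305), while the list in NZM kept its call under both settings. In iNZM the list fell in 11 of 17 with 0 rising (13 and 0 adjusted over the list alone, camera adjusted p = 1.93e-05, and adjusted p = 0.324 with an estimated correlation). Without those libraries it changed sign and lost the call (0.896). In WT they fell in 11 of 17 with 0 rising (15 and 0 adjusted over the list alone, camera adjusted p = 1.52e-05, and adjusted p = 0.917 with an estimated correlation). Actn3, a fast muscle fibre gene, fell by 2.62 ± 0.58 (SE, limma adjusted p = 0.000647) in WT. Mitochondrially encoded genes fell in 8 of 9 after chronic UVB in NZM with 0 rising (9 and 0 adjusted over the list alone, camera adjusted p = 3.18e-06, and adjusted p = 0.631 with an estimated correlation). Ribosomal protein genes fell in 10 of 15 after acute UVB in NZM with 0 rising (14 and 0 adjusted over the list alone, camera adjusted p = 1.75e-06, and adjusted p = 0.515 with an estimated correlation). Pyy, a peptide hormone gene, fell after each UVB regimen, by 7.40 ± 0.94 after acute and 6.10 ± 0.94 after chronic UVB in NZM.

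The tests below were chosen before the results were seen, except the test of clone and pseudogene models. Genes near Ifnar1 were tested for a passenger segment of chromosome 16, because an altered locus crossed into another line carries its neighbours. Within 20 Mb, 0 of 118 tested genes had the same sign and an unadjusted p below 0.05 between iNZM and NZM in every regimen, against 36 of 15269 elsewhere, or 0.236% (Fisher's exact p = 1). This cannot be told apart from a segment without effect, because only 0.278 genes were expected near the locus, so the value set in advance to count against a segment was wrong. Gene models named after clones or as pseudogenes made up 22.7% of the genes called between NZM and WT without UVB and 12.1% of those called after acute UVB in NZM, against 20.4% of tested genes. The share differed between the comparisons (Fisher's exact p = 1.61e-40 over genes called in only 1 of them), mostly through the low share after UVB, and strain calls against all tested genes gave a weaker difference (Fisher's exact p = 0.000396). Sequence differences between strains that move reads between near-identical copies are a possible explanation of this small excess, which was not tested on reads.

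Counts of called genes were set against 100 splits of the same libraries, the real one included. For UVB against none, as many genes as in the real split were called in 1 of 100 splits for acute UVB in NZM (highest other 868), 2 in iNZM (5148) and 1 in WT (3068). For chronic UVB the figures were 1 in NZM (888), 2 in iNZM (5951) and 1 in WT (3571). For NZM against WT they were 1 without UVB (1573), 1 after acute (791) and 1 after chronic UVB (494). For iNZM against NZM they were 1 without UVB (highest other 3), 10 after acute UVB (2826) and 10 after chronic UVB (5938), against real counts of 6, 43 and 82. For the response of NZM against WT they were 3 for acute (674) and 2 for chronic UVB (1468), and for chronic against acute UVB over the strains 1 (3992). For the response of iNZM against NZM they were 7 for acute UVB (highest other 1) and 100 for chronic UVB (2013). Chance can therefore not be excluded for the counts of iNZM against NZM after acute and chronic UVB, nor for the counts of both responses of iNZM against NZM. In iNZM against NZM after acute and chronic UVB, splits that called many times the real count point to a structure of the samples other than strain, and the hair follicle scores above 5 lie in both strains.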
